A study of Mus musculus with 6 samples.

How the data were processed

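The samples were 6 mouse RNA libraries of exosomes, 3 from immature and 3 from mature bone marrow-derived dendritic cells. Per the labels' protocols, marrow cells were cultured to day 7 with 20 ng/ml GM-CSF and 10 ng/ml IL-4, mature cells received 5 µg/ml lipopolysaccharide for 24 h, and exosomes were collected by differential ultracentrifugation after a further 48 h of culture. RNA was extracted with Trizol and libraries were made from 1 µg with an Illumina TruSeq kit, per the labels' protocols. Groups and replicate numbers were taken from the sample titles. A treatment tag in the labels reads untreated for all 6 samples, which the protocol of the mature arm contradicts, and it was not used.

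The authors deposited one FPKM value per transcript and library (fragments mapped to a transcript, scaled by its length and by the library's mapped fragments), per the file headers. The submitters' processing notes name cutadapt, HISAT2 2.0.5, STAR 2.5.2b and StringTie, with no role or order, and the human build hg19. The rows carry mouse Ensembl identifiers, and 11310 of the 11331 genes whose symbol has a RefSeq position overlapped it on the mouse build GRCm38 (99.81%), so positions are given as the table lists them and read on GRCm38. Of 12384 gene identifiers 12359 were found in a table of gene names. Every listed transcript reached an FPKM of 0.5 in at least 1 library, the smallest maximum being 0.500024. Abundances estimated per isoform depend on how reads were divided among the transcripts of a gene, and paralogs and overlapping genes may share reads.

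Transcripts of 5 types other than protein coding (processed transcripts, lincRNA, TEC, sense intronic and sense overlapping) were taken as non-coding, 5482 in all, of which 1184 came from genes with no coding transcript. Such a gene had no coding transcript among those listed, and RefSeq did not class its symbol as protein coding. Gene values were sums of FPKM over the transcripts of a gene. Features at an FPKM of at least 0.5 in at least 3 of the 6 libraries were tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend and robust options) on log2(FPKM + 1), with no further scaling and no replicate block, and Benjamini-Hochberg adjusted p under 0.05 was the threshold. Count models were not used because FPKM values are not counts. Per-library values were compared with 2-sided exact permutation tests.

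The 25 gene lists were fixed before the data were examined, as were the tests and the alternatives unless said otherwise. Lists with at least 5 tested members, 22 of the 25, were tested with camera at a preset correlation of 0.01 and again with an estimated correlation. Camera called 12 lists, 8 higher and 4 lower, and 0 with an estimated correlation, where 3 had an unadjusted p under 0.05. B and plasma cell genes, abundant structural non-coding RNAs and microRNA host genes had 3, 1 and 3 tested members and 0 past the test over all genes, adjusted over the list alone or at an unadjusted p under 0.05.

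The naming rule took, among transcripts past the threshold whose groups did not overlap, up to 10 per direction by fold change, up to 8 per direction for non-coding transcripts or, where none passed, the 5 with the smallest p, and up to 4 members per list, those past the threshold first and then the most abundant. One item that the rule named is not reported here. It added Itgax, Cd86, Cd40, H2-Ab1, Cd9, Cd63, Cd81, Malat1, Neat1 and Ptgs2os2 as check genes. Ptgs2os2 did not pass the filter, at 0.465 and 0.518 FPKM in mature libraries 1 and 3 and listed at 0 in the other 4.

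The procedures were tested on simulated data with the spread of the real features. For genes, 6%, 40%, 96% and 100% of 50 features changed by 1, 2, 4 and 6 on the log2 scale were recovered, with 8 false calls among 10277. For transcripts the shares were 0%, 26%, 92% and 100%, and for non-coding transcripts 2%, 24%, 92% and 100%. Simulated values could fall below 0 on the log2(FPKM + 1) scale, which real values cannot. The shares therefore do not apply to decreases of features with low values. Gm20492, at a mean of 5.13 FPKM in the immature libraries and 0 in the mature ones, had a gene-level log2 fold change of only -2.28. Camera recovered the shifted list and called 0 others. The simulated genes varied independently of each other, so this does not show how often camera calls lists whose genes vary together.

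FPKM does not give read totals. Relative depth was estimated from 5787 genes with a single transcript, where low values of 2 libraries that hold equal whole reads differ by a fixed ratio, with a joint fit over the 15 library pairs in Python 3.11.15 with numpy 2.4.6. The fit placed 249 ratios within a log tolerance of 0.005, against at most 210 in 99 fits with the pairs shifted at random. The relative depths were 1.15 and 0.992 for immature 2 and 3, and 1.19, 0.907 and 0.754 for mature 1, 2 and 3, against immature 1. Bootstrap intervals of what 1 read is worth spanned up to about a factor of 2 (0.433 to 0.875 for immature 2), so these depths are approximate.

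Alternatives covered the pseudocount, the filter, scaling, moderation, library weights, thresholds, the replicate block and each library left out in turn. Leaving out or modelling the 2 libraries with the fewest detected transcripts, gene-by-gene library weights, the narrower non-coding definition, 2 scalings for lists and leaving out libraries with the features of all 6 kept were chosen after seeing the data.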

Results

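RNA carried by exosomes, the small vesicles that cells release, was profiled for mouse dendritic cells grown from bone marrow. One group held exosomes from immature dendritic cells and the other held exosomes from mature dendritic cells, whose cultures had received lipopolysaccharide, a bacterial cell wall component that activates these cells. Each group had 3 libraries, and the study asked how the long RNAs of the exosomes, long non-coding RNAs in particular, differed between the groups. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

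The table held 27544 transcripts of 12384 genes with an FPKM value in each library. The number of transcripts at an FPKM of at least 0.5 was 15432, 10912 and 16728 in immature libraries 1, 2 and 3, and 12924, 18775 and 17604 in mature libraries 1, 2 and 3. The mean was 14360 ± 3053 (SD, n = 3) in the immature group and 16430 ± 3096 in the mature group, a difference smaller than the spread between libraries (2-sided exact permutation p = 0.5, where 3 against 3 cannot go below 0.1). Without immature library 2 the difference of 2077 transcripts was 354, without mature library 2 it was 907, and without immature library 3 or mature library 1 it was 3262 or 3832. The FPKM values summed to 145370, 135814 and 213737 in the immature libraries and to 130401, 281368 and 245683 in the mature libraries. The most abundant transcripts on average over the 6 libraries were Fth1-201 and Ftl1-201, which encode the ferritin chains, and Chil3-201, which encodes a chitinase-like protein of myeloid cells. Fth1-201 stood between 1804 and 3769 FPKM in the immature libraries and between 6319 and 10006 FPKM in the mature libraries. Total read numbers are unknown, since the values are not counts.

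Immature library 2 and mature library 1 stood apart from the other 4 libraries. Mitochondrially encoded transcripts made up 2.55% and 0.94% of the summed FPKM in these libraries, against 0.0696% to 0.282% in the other 4. Ribosomal protein transcripts made up 12.5% and 11.8% there, and 23.6%, 33.6%, 19.5% and 13.1% in immature 1, immature 3, mature 2 and mature 3.

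**Figure D1:**
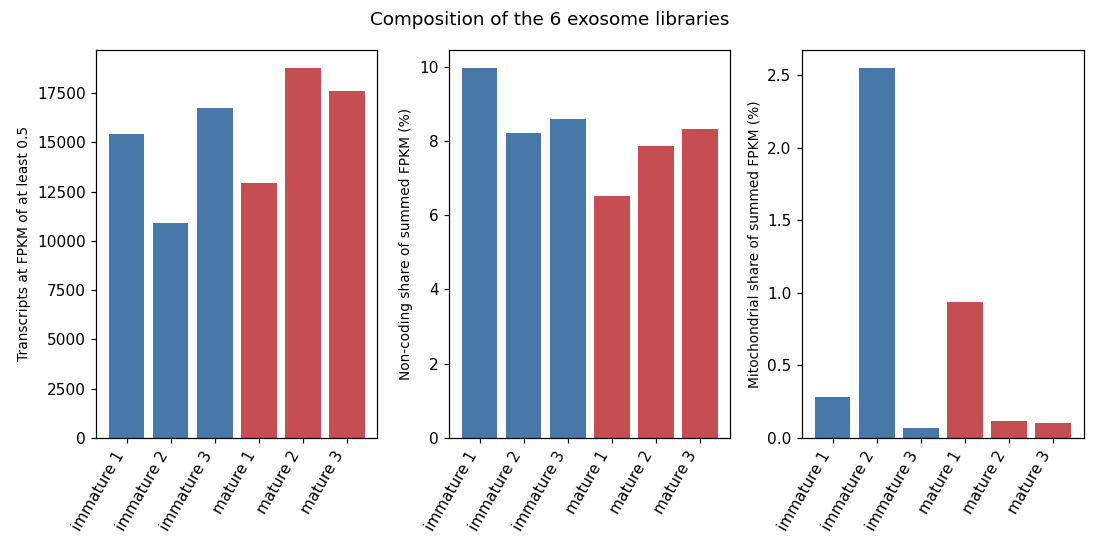
Bars give, for each of the 6 libraries, the number of transcripts at an FPKM of at least 0.5, the non-coding share of the summed FPKM in percent and the mitochondrial share of the summed FPKM in percent, with immature libraries in blue and mature libraries in red. Immature 2 and mature 1 have the fewest detected transcripts, 10912 and 12924, and the highest mitochondrial shares, 2.55% and 0.94%.

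At the level of genes, inflammatory and interferon-response genes were higher in exosomes from mature cells. Saa3, an acute-phase serum amyloid gene, rose from 1.68 ± 0.70 FPKM (SD, n = 3) to 445 ± 368 FPKM, a log2 fold change of 6.98 (SE 0.70, limma adjusted p = 0.00497). Il1a and Il1b, which encode interleukin-1 alpha and beta, rose from 3.08 ± 0.48 to 67.0 ± 13.4 FPKM and from 6.64 ± 4.98 to 170 ± 55.8 FPKM. The chemokine genes Cxcl3 and Ccl5 rose from 11.2 ± 5.41 to 230 ± 111 FPKM and from 54.9 ± 39.7 to 1238 ± 367 FPKM. Of 10277 genes tested, 19 were higher and 0 were lower in the mature group (limma, Benjamini-Hochberg adjustment), and at an unadjusted p under 0.05 the counts were 978 higher and 23 lower.

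Hamp, which encodes the iron-regulating hormone hepcidin, was listed at 0 in the 3 immature libraries and at 51.2, 46.7 and 74.2 FPKM in the mature libraries (limma adjusted p = 0.000847). Cxcl1, a neutrophil-attracting chemokine gene, was likewise listed at 0 in the 3 immature libraries and at 13.4, 32.6 and 26.4 FPKM in the mature ones (limma adjusted p = 0.00497). Cfb, which encodes complement factor B, had a log2 fold change of 6.14 (SE 0.66, limma adjusted p = 0.00497). Acod1, the gene of the itaconate-producing enzyme, and Clec4e, a pattern-recognition receptor gene, rose by log2 3.90 (SE 0.54) and 3.62 (SE 0.52). Ptgs2 and Ptges, which encode consecutive enzymes of prostaglandin E2 synthesis, both passed the test. Ptgs2 had a log2 fold change of 3.30 (SE 0.49), and Ptges was at 0.40, 0 and 1.14 FPKM in the immature libraries and at 11.3, 24.3 and 52.6 FPKM in the mature libraries. Cd14, the lipopolysaccharide co-receptor gene, rose by log2 3.21 (SE 0.50), and Procr, which encodes the endothelial protein C receptor, by log2 4.41 (SE 0.69). Cfb, Acod1, Clec4e, Ptgs2, Ptges and Procr, the most abundant transcripts above, and Gm26736 and Snhg5 below lie outside the naming rule and were chosen after their values were seen.

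Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. The median gene was itself 0.38 higher on the log2 scale in the mature group, and 16.7% of genes had all 3 mature values above all 3 immature values while 0.642% had them all below, where chance gives 10% for both directions together. Scalings that remove this shift changed the split at an unadjusted p under 0.05 to 480 higher and 237 lower with median-of-ratios scaling, 461 and 258 with upper-quartile scaling, and 437 and 332 with quantile normalization. The count past the test was then 12, 14 and 14 genes, all higher. The count was 7 without immature library 1, 6 without mature library 2 and 0 without mature library 3, and 61 (60 higher, 1 lower) without both immature library 2 and mature library 1. The filter, applied again, dropped 4 of the 19 genes when a mature library was left out, and over the genes tested with all 6 libraries the counts were 13 without mature 2, 1 without mature 3 and 73 without both immature 2 and mature 1.

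**Figure D2:**
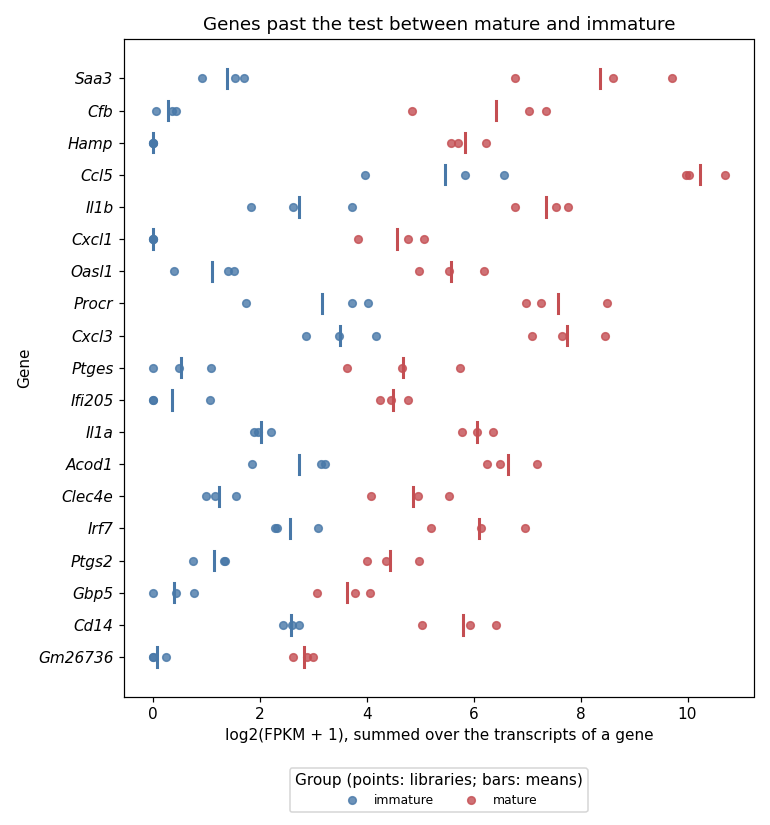
Each point is one library's log2(FPKM + 1) for a gene that passed the test between the groups, with immature libraries in blue, mature libraries in red and short bars at the group means. All 3 mature libraries lie above all 3 immature libraries for each of the 19 genes, which were selected for passing the test.

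Interferon-stimulated genes were higher in the mature group as a list. Of its 35 tested members, 4 rose in the test over all genes and 34 when adjusted over the list alone, and the median log2 fold change was 2.30. Oasl1, an oligoadenylate synthetase-like gene, rose from 1.27 ± 0.84 to 49.5 ± 21.3 FPKM, and Irf7, a transcription factor gene of the interferon response, rose from 5.12 ± 2.07 to 76.5 ± 44.7 FPKM. Ifi205 was at 1.11, 0 and 0 FPKM in the immature libraries and at 20.9, 18.1 and 26.2 FPKM in the mature ones, and Gbp5, a guanylate-binding protein gene, at 0, 0.714 and 0.347 against 12.7, 15.6 and 7.35 FPKM. Of the 32 tested NF-kB and inflammatory cytokine genes, 9 rose over all genes and 25 when adjusted over the list alone, with a median log2 fold change of 2.36. Both lists passed camera with its preset correlation (adjusted p = 2.82e-35 and 1.04e-29). Both calls ended with adjusted p = 0.213 and adjusted p = 0.217 with an estimated correlation.

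Among 27 tested dendritic cell maturation markers, 1 rose over all genes, Ccl5, and 13 rose when adjusted over the list alone, with a median log2 fold change of 1.57. Ccl22, a chemokine gene of mature dendritic cells, was at 73.2 ± 42.8 and 348 ± 75.1 FPKM, and Tnfrsf9 at 55.8 ± 42.4 and 195 ± 94.8 FPKM, and neither passed the test over all genes. Ccl17 was at 880 ± 203 and 1500 ± 470 FPKM. The list passed camera (adjusted p = 1.17e-12), with adjusted p = 0.282 with an estimated correlation. The co-stimulatory gene Cd40 was at 0.593 ± 0.563 and 3.77 ± 1.73 FPKM (limma adjusted p = 0.33), and Cd86 at 8.98 ± 8.92 and 18.2 ± 1.33 FPKM (limma adjusted p = 0.525). Itgax, the CD11c gene, was at 29.2 ± 24.0 and 24.9 ± 6.35 FPKM (limma adjusted p = 0.974).

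For antigen presentation, the 19 tested genes of MHC class I had a median log2 fold change of 1.51 and passed camera (adjusted p = 2.99e-08), with adjusted p = 0.442 with an estimated correlation. Over all genes or adjusted over the list alone 0 members passed limma, and 12 were higher at an unadjusted p under 0.05. B2m, the shared light chain, was at 801 ± 634 and 2621 ± 1189 FPKM, and H2-D1 at 243 ± 168 and 616 ± 256 FPKM. The 13 tested genes of MHC class II did not pass camera (adjusted p = 0.449), and 0 members passed limma over all genes, adjusted over the list alone or at an unadjusted p under 0.05. Cd74, the invariant chain gene, was at 458 ± 178 and 936 ± 460 FPKM, and H2-Ab1 at 284 ± 85.1 and 561 ± 95.4 FPKM (limma adjusted p = 0.594).

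The exosome biogenesis and cargo list, with 36 tested members and a median log2 fold change of 0.75, was called higher (adjusted p = 0.00777), with adjusted p = 0.729 with an estimated correlation. Over all genes or adjusted over the list alone 0 members passed limma, and 5 were higher at an unadjusted p under 0.05. The tetraspanin genes Cd63, Cd9 and Cd81, whose proteins mark exosomes, were at 57.9 ± 29.2, 65.9 ± 46.2 and 6.22 ± 2.43 FPKM in the immature group and 106 ± 49.0, 121 ± 70.4 and 12.9 ± 4.26 FPKM in the mature group. Their limma adjusted p-values were 0.678, 0.723 and 0.56. Stress and apoptosis genes had a median log2 fold change of 1.12, with 0 of 24 past the test over all genes, 7 when adjusted over the list alone and 11 at an unadjusted p under 0.05. Hmox1, the heme oxygenase gene, was at 99.7 ± 97.4 and 332 ± 155 FPKM. Glycolysis and hypoxia genes had a median of 0.89, with 0 of 23 past either test and 5 higher at an unadjusted p under 0.05, and Ldha, the lactate dehydrogenase A gene, was at 222 ± 66.7 and 496 ± 156 FPKM. These lists passed camera (adjusted p = 1.98e-07 and 0.000117), with adjusted p = 0.439 and adjusted p = 0.442 with an estimated correlation. Without immature library 3 the exosome and glycolysis calls ended (adjusted p = 0.406 and 0.0973), and the exosome call also ended with a pseudocount of 0.1 and with upper-quartile or median-of-ratios scaling (adjusted p = 0.0607, 0.108 and 0.112).

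Cytosolic ribosomal protein genes were called lower relative to other genes. Their median log2 fold change was -0.25 over 82 members, 0 of which passed limma over all genes, adjusted over the list alone or at an unadjusted p under 0.05 (camera adjusted p = 4.07e-12, adjusted p = 0.719 with an estimated correlation). Rps29 was at 1983 ± 1745 and 1286 ± 758 FPKM. Cell cycle genes had a median of -0.14 over 24 members and 11 mitochondrially encoded genes a median of -0.30, with 0 members past limma over all genes, adjusted over the list alone or at an unadjusted p under 0.05. Mki67, a proliferation marker gene, was at 30.8 ± 33.8 and 19.1 ± 15.3 FPKM, and mt-Nd1 at 120 ± 152 and 60.5 ± 29.2 FPKM. Camera called both lower (adjusted p = 0.000378 and 0.00107), with adjusted p = 0.744 and adjusted p = 0.515 with an estimated correlation. For the 68 histone genes the median log2 fold change was 0.08, opposite in sign to the camera call of lower (adjusted p = 0.00189, adjusted p = 0.81 with an estimated correlation), and it was -0.42 with median-of-ratios scaling. No histone gene passed over all genes or adjusted over the list alone (0 members, 1 higher at an unadjusted p under 0.05). The mitochondrial call ended without immature 2, mature 2 or mature 3 (camera adjusted p = 0.813, 0.0586 and 0.0693) and with quantile normalization (0.0561). The histone call ended without immature 3 or mature 1 (0.692 and 0.122), and the cell cycle call without immature 3 (0.414). Relative to all genes, the mitochondrial median turned to 0.23 without immature 2 and the histone median to 0.12 without immature 3. In immature 2 and mature 1, the libraries with few detected transcripts, the ribosomal protein list medians lay 0.95 and 1.03 below the 6-library mean on the log2 scale.

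Among markers of other cell types, mast cell, basophil and eosinophil genes were called higher. The 10 tested members had a median log2 fold change of 1.30 (camera adjusted p = 0.0137, adjusted p = 0.442 with an estimated correlation), with 0 past the test over all genes, 3 when adjusted over the list alone and 5 at an unadjusted p under 0.05. This call ended without immature 1 or immature 3 (adjusted p = 0.0758 and 0.0736). Hdc, the histidine decarboxylase gene, was at 2.57 ± 1.80 and 21.9 ± 13.1 FPKM. Camera gave adjusted p = 0.519 for neutrophil and granule genes, 0.762 for macrophage and monocyte markers, 0.762 for dendritic cell identity genes, 0.795 for T and NK cell genes, 0.936 for erythroid and platelet genes and 0.393 for stromal and endothelial genes. Cd14 was the 1 gene of these 6 lists that passed the test, over all genes or adjusted over the list alone, and at an unadjusted p under 0.05 each list had 0 to 3 members higher and 0 lower. S100a8, a neutrophil calprotectin gene, stood at 69.2, 88.9 and 517 FPKM in the immature libraries and at 63.5, 397 and 134 FPKM in the mature libraries. Nuclear oxidative phosphorylation genes gave adjusted p = 0.762, with 0 members past either test and 2 higher at an unadjusted p under 0.05. Single libraries decided several of these calls. Without immature 3 the neutrophil list was called higher (adjusted p = 2.06e-05) and the macrophage list lower (0.0246), while without both immature 2 and mature 1 the macrophage list was called higher (0.0487), though not over the genes tested with all 6 libraries. Without mature 2 the stromal list was called higher (0.00078), and without immature 2 the T and NK cell list (0.0465) and, over the genes tested with all 6 libraries, the stromal list (0.0353).

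**Figure D3:**
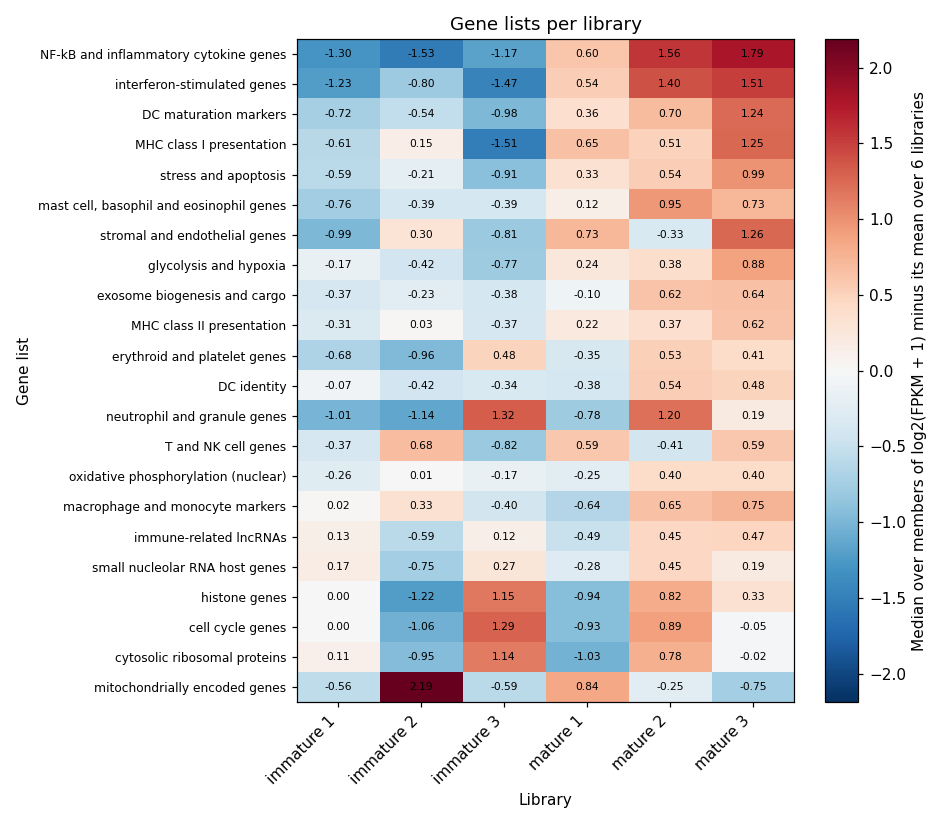
Each cell gives, for one gene list and one library, the median over the list's tested genes of log2(FPKM + 1) minus the gene's mean over the 6 libraries, with red above and blue below that mean. The NF-kB list runs from -1.53 to -1.17 in the immature libraries and from 0.60 to 1.79 in the mature libraries, while the cell cycle list is lowest in immature 2, at -1.06, and highest in immature 3, at 1.29.

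Single transcripts of several of these inflammatory genes were higher in the mature group, largely on the same values as their gene sums. Of 15972 transcripts tested, 10 were higher and 2 were lower in the mature group (limma), with 1181 higher and 109 lower at an unadjusted p under 0.05. Saa3-201, Hamp-201, Il1b-201, Il1a-201, Cxcl1-201, Ifi205-201 and Irf7-202 were higher, the last at 0, 0.455 and 0 FPKM in the immature libraries and at 14.9, 22.7 and 63.8 FPKM in the mature libraries. Hamp-201, Il1a-201, Cxcl1-201 and Ifi205-201 were the only listed transcripts of their genes, so their values equal the gene sums. The other transcripts of Saa3 and Il1b summed to at most 7.35 and 0.695 FPKM in any library. These calls therefore add little to the gene calls. Cdc34-208, a transcript of a ubiquitin-conjugating enzyme gene, was listed at 0 in the immature libraries and at 12.0, 11.0 and 12.7 FPKM in the mature libraries. Aprt-209, from the gene of an adenine salvage enzyme, fell from 30.1, 46.3 and 28.0 FPKM to 0.078, 0.0491 and 0.0367 FPKM (log2 fold change -5.05, SE 0.50, limma adjusted p = 0.0122). Ywhag-205, from a 14-3-3 protein gene, was at 16.1, 29.1 and 21.3 FPKM in the immature libraries and listed at 0 in the mature libraries (limma adjusted p = 0.0227). The gene sums of Cdc34, Aprt and Ywhag did not pass the test, with log2 fold changes of 0.69, 0.28 and 0.27. The count of transcripts past the test was 0 to 4 when any 1 library was left out (0 to 7 over the transcripts tested with all 6 libraries), 0 without both immature 2 and mature 1, and 6 (4 higher, 2 lower) under each of the 3 other scalings.

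Few non-coding transcripts passed the test. Of 2026 tested, 2 were higher and 0 were lower in the mature group, both over all transcripts and adjusted over non-coding transcripts alone (limma), and 118 were higher and 29 lower at an unadjusted p under 0.05. Both are processed transcripts of protein-coding genes. Cd52-203, on chromosome 4 at 134082448 to 134095041, comes from the gene of a leukocyte surface glycopeptide and was at 29.2, 39.7 and 36.9 FPKM in the mature libraries (limma adjusted p = 0.0118). Oasl1-203, on chromosome 5 at 114923435 to 114936067, was at 28.2, 11.8 and 38.3 FPKM there (limma adjusted p = 0.0341). The immature libraries listed both at 0. The gene sum of Cd52 did not pass the test (log2 fold change 0.60, limma adjusted p = 0.77), while that of Oasl1 did. Among the lower ones with the smallest p, none past the test, were Tpd52-208, H2afz-205, Dennd4c-203 and Gm20492-201, with limma adjusted p between 0.342 and 0.353. Tpd52-208 was at 4.01, 8.71 and 5.71 FPKM in the immature libraries and at 0, 1.89 and 0 FPKM in the mature libraries.

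Of the 422 tested non-coding transcripts whose gene had no coding transcript, limma called 0, with 14 higher and 5 lower at an unadjusted p under 0.05. At gene level 1 of 360 such genes rose, Gm26736, at 0, 0.183 and 0 FPKM in the immature libraries and 6.99, 5.15 and 6.40 FPKM in the mature ones (limma adjusted p = 0.0333). Gm26736 passed in 11 of the 24 alternatives in which it was tested, with adjusted p up to 0.278, and in none of the 3 other scalings. Of 22 tested immune-related long non-coding RNAs, 0 passed limma over all genes, 3 were higher at an unadjusted p under 0.05 and 2 rose when adjusted over the list alone, AW112010 and Snhg5. AW112010 was at 31.0 ± 21.8 and 221 ± 124 FPKM, and Snhg5 at 0, 0 and 3.07 FPKM against 5.67, 5.61 and 7.23 FPKM. Malat1 was at 525 ± 412 and 283 ± 48.3 FPKM and Neat1 at 12.9 ± 2.16 and 13.7 ± 3.80 FPKM (limma adjusted p = 0.882 and 0.983). This list and the small nucleolar RNA host genes gave camera adjusted p = 0.12, and 0 of the 13 tested host genes passed either test, with 1 higher at an unadjusted p under 0.05. Without mature 3, over the genes tested with all 6 libraries, the immune-related list was called lower relative to other genes (camera adjusted p = 0.0173). Over the non-coding transcripts tested with all 6 libraries, the count past the test was 0 without immature 1, immature 2 or mature 3, 1 without immature 3 or mature 1, and 2 without mature 2.

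Non-coding transcripts made up 8.92 ± 0.925% (SD, n = 3) of the summed FPKM in the immature group and 7.57 ± 0.929% in the mature group, a difference that did not pass the test (2-sided exact permutation p = 0.2). Those of genes with no coding transcript made up 4.55 ± 0.619% and 4.02 ± 1.06% (2-sided exact permutation p = 0.6). The difference of -1.35 percentage points was -0.828 without immature 1, -0.831 without mature 1 and -0.810 without the 10 most abundant transcripts. Counted as a share of detected transcripts the difference changed sign, to 0.0867 percentage points higher in the mature group (2-sided exact permutation p = 1).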

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

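The gene-by-gene weights, the 2 low-detection alternatives, the narrower non-coding definition, 2 scalings for lists and leaving out libraries with the features of all 6 kept were chosen after seeing the data, and the cause of the changes below was not tested except where named. DESeq2 and TMM were planned only for counts and were not run. Counts past the test are given for transcripts, non-coding transcripts and genes in that order, against 12, 2 and 19. A pseudocount of 0.1 gave 9 genes, and 0.01 gave 0, 0 and 5. Quantile, upper-quartile and median-of-ratios scaling each gave 6 transcripts and 1 non-coding transcript, the last with 12 genes, 11 of them among the 19. Library weights from arrayWeights gave 2548, 269 and 6396, but the gene fit stopped before convergence and gave immature 1 a weight of 38.2, so that it rested largely on that library. Gene-by-gene weights gave 407, 43 and 2138. An unadjusted p with a log2 fold change of at least 1 gave 1230, 136 and 952. Leaving out 1 library gave 0 to 4, 0 to 0 and 0 to 27, with 0 genes without mature 3. The filter, applied again, dropped features at 0.5 FPKM or more in the mature group alone when a mature library was left out (6 of the 12 transcripts, both non-coding ones and 4 of the 19 genes). With the features of all 6 kept, leaving out 1 library gave 0 to 7, 0 to 2 and 1 to 27, with 7 genes without immature 1, 13 without mature 2 and 1 without mature 3. Without both immature 2 and mature 1 the counts were 0, 0 and 61 (14 among the 19), or 0, 0 and 73 (19 among the 19) with the features kept, and a low-detection term gave 22 transcripts and 169 genes. The narrower non-coding definition gave 0. The replicate block gave 0, 0 and 5. Same-numbered libraries did not deviate together (r = -0.028, -0.448 and -0.128 across genes) and none correlated best with its own number. The strongest match was immature 3 with mature 2 (r = 0.531), and immature 1 matched mature 3 best (r = 0.118). Immature 2 correlated best with mature 1 (r = 0.382), the other library with few detected transcripts. Such differences between libraries could hide a pairing, so these correlations cannot tell whether the numbers pair the samples. A pairing or batch across the groups under other numbers was not tested, and the main test was unpaired.

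Camera called 12 lists, 9 to 13 when 1 library was left out, 11 to 13 under other settings, 12 under the replicate block and 0 with an estimated correlation. The non-coding share, lower by 1.35 points in the mature group, differed by 0.0867 as a share of detected transcripts and ranged from -1.72 to -0.828 when 1 library was left out. Detected transcripts ranged from 354 to 3832 higher. Called genes kept their direction in all 515 alternatives and their side of the threshold in 370, and called transcripts in 140 of 304, with no change of direction. The groups did not overlap for any called gene or transcript, so alternatives other than the scalings could not turn the direction. Hamp passed in the 24 alternatives in which it was tested, with adjusted p up to 0.0233, and Cfb and Cxcl1 in 23 of 24, with 0.0793 without mature 3. These genes were not tested in the 4 alternatives where the filter dropped them. With arrayWeights mt-Nd1 turned to 0.94 and Cox8a to 0.60. Relative to all genes the mitochondrial list turned to 0.23 without immature 2 (lowest -1.49, without immature 3), the histone list to 0.12, or 0.14 with the features kept, without immature 3 (lowest -0.67, without immature 2), and the macrophage list to 0.40 without both low-detection libraries. Named genes and lists past the threshold in neither fit changed sign in 206 of 2399 and 41 of 210 alternatives, and these are not counted as reversals. At this spread a log2 change of 2 was recovered for 40% of simulated genes, so smaller differences were mostly not detectable.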

Other observations

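All tests here except the count of transcripts on in one group and off in the other were chosen after the result was seen. The medians of the neutrophil and granule, histone and cell cycle lists were highest in immature 3 and mature 2, one library of each group, although single members differed. Hbb-bs, a beta globin gene, was at 6.01, 7.87 and 167 FPKM in the immature libraries and at 12.0, 88.0 and 5.60 FPKM in the mature libraries, and Ngp, a neutrophil granule gene, at 28.8, 40.5 and 249 against 55.5, 310 and 91.0 FPKM. The cell cycle list medians were 1.29 and 0.89 above the 6-library mean on the log2 scale in these libraries, and the histone list medians 1.15 and 0.82. A few predicted genes, Gm10800 and similarly named rows picked after their values were seen, made up 2.12% and 0.339% of the summed FPKM in immature 2 and mature 1, against 0.00512% to 0.0359% in the other 4. Xist, expressed from the inactive X chromosome of female cells, was at 4.59 and 1.19 FPKM in those libraries and at most 0.0155 FPKM elsewhere, while the Y-linked gene Ddx3y lay between 1.15 and 4.67 FPKM in all 6. Xist and Ddx3y were also picked after their values were seen.

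Immature 2 and mature 1 detected the fewest transcripts. Shallower sequencing would make 1 read worth more FPKM there, yet the fit put it at 0.771 times that in the other 4 libraries (bootstrap interval 0.385 to 0.777). Resampling moved the worth in single libraries by about a factor of 2 (1.003 to 2.008 for immature 3). The fit therefore argues against shallower sequencing only as far as its approximate depths hold. A swap of their labels would place the inflammatory and interferon genes of immature 2 above those of mature 1, but the median over 67 genes was 1.619 higher on the log2 scale in mature 1, against a gap of at most 0.084 within a group among the other 4 libraries. Mature 1 itself, at 0.543, lay well below mature 2 and 3, at 1.527 and 1.611. These medians therefore speak only to a full swap. What sets these libraries apart, such as a mixed source of cells or genomic DNA, was not tested and remains open, as does a biological difference.

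Inflammatory and interferon genes were higher in the mature group, with a median log2 fold change 1.97 above that of all genes over 67 genes. Library scaling moves the genes of a library together, and the median gene rose by only 0.38. It could therefore account for only a small part of the list median of 2.353. Quantile normalization left that median at 1.907, with 65 of the 67 genes above 0, and could not have taken most of it away. If the 2 libraries with few detected transcripts carried the difference, the value of 1.97 above all genes would fall without them, but it was then 2.238. The filter was applied again there and dropped list genes such as Cxcl1. A rise was foreseeable, since immature 2 and mature 1 had the list medians nearest to each other across the groups, at -1.076 and 0.543. In the other 4 libraries the medians were -1.228 and -1.291 (immature) and 1.527 and 1.611 (mature), so the difference was present without these 2. These values argue against both as the whole cause. The lipopolysaccharide given to the mature group remains a candidate explanation that the design does not separate from other differences between the cultures.

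A pattern at the level of isoforms was that transcripts such as Aprt-209, Ywhag-205, Cd52-203 and Cdc34-208 were on in one group and off in the other while their gene was on in both. Counting transcripts at 5 FPKM or more in one group and under 0.1 in the other, with the gene at 5 or more in every library, gave 6 in the real split of the libraries and at most 5 in the other 9 splits. Separate quantification of the groups could leave such transcripts, but 6 is neither 3 times the highest other split nor within it, so the count does not decide. Reads may also have been reassigned between isoforms, and for 1 of the 4 called transcripts whose gene was not called, Aprt-209, the rest of the gene was apart in the opposite direction, while for the other 3 it overlapped. Despite the overlap, the rest of Ywhag had a log2 fold change of 2.20 while Ywhag-205 fell, against 0.40 for the rest of Cd52 and -0.07 for that of Cdc34. These explanations cannot be told apart from a change of isoform with estimated abundances alone.

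With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 19 genes and the highest other 2, and it gave 12 transcripts against 3 and 2 non-coding transcripts against 1, so 1 of the 10 splits, the real one, reached each count. For gene lists under camera with the preset correlation, 5 of the 10 splits called at least the 12 lists of the real split and the highest called 16, so the number of lists called under this setting does not set the groups apart from other splits.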
